A study of Homo sapiens with 8 samples.

How the data were processed

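RNA-seq and Ribo-seq libraries were made from wild-type HEK293T and ZNF598-null cells, with 2 libraries per genotype and assay (8 libraries in 4 groups). Per the labels' protocols, untreated cells were harvested a day after plating, total RNA was purified on columns and converted with a TruSeq kit, and footprints were prepared by an established Ribo-seq procedure with later modifications. Groups and replicate numbers were taken from the sample titles.

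The deposited count tables held whole-number read counts per gene symbol for 27011 genes, 1 column per library, with a gene length. Per the submitters' processing notes, Bowtie2, TopHat2 and edgeR were used with the hg19 genome. The counting tool, its strand setting and its treatment of reads that map to several places were not given in the sources used here. Of 11246 genes with at least 100 footprint counts in total, 70 had the same counts as another gene in all 8 libraries, so some reads were counted on more than 1 gene copy or on overlapping genes. Per the file headers, the authors' comparison tables gave a log2 fold change, a mean log2 CPM, a p-value and an adjusted p-value for each assay. Per the file headers, the authors' table of translational efficiency gave a ratio of footprints to mRNA per genotype, the log2 of their ratio and p-values. The tool behind it was not given in the sources used here. The authors' p-values and ratios were used only to describe those tables.

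Counts were analysed as deposited in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, genotype as the group), libraries were scaled by TMM, and the quasi-likelihood test (glmQLFit with robust estimation, glmQLFTest) compared null with wild-type cells within each assay. Translational efficiency was tested as the interaction of assay and genotype in 1 model over the 8 libraries, on genes kept in both assays, with TMM factors computed within each assay. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Standard errors are the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic. At these total counts and this spread between replicates (common biological coefficient of variation 6.18% in RNA-seq and 11.1% in Ribo-seq), the median standard error of a log2 fold change was 0.094 in RNA-seq, 0.20 in Ribo-seq and 0.20 in translational efficiency. Poisson intervals (95%, exact) cover counting error only.

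The 25 gene lists were fixed before the data were examined: ribosome collision sensing and quality control, the 4EHP-GIGYF complex, mRNA decay, nonsense-mediated decay, the integrated stress response, the unfolded protein response, heat shock, interferon-stimulated genes, immediate-early mRNAs, p53 targets, cytosolic and mitochondrial ribosomal proteins, translation factors, aminoacyl-tRNA synthetases, oxidative phosphorylation, mitochondrially encoded proteins, cholesterol synthesis, hypoxia and glycolysis, proliferation, histones, proteasome subunits, selenoproteins, and neuronal, renal and mesenchymal markers. They were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a correlation preset at 0.01, over the 24 lists with at least 5 tested members. None of the mitochondrially encoded genes had a row in the count tables, so that list was not tested. The median, mean and camera direction differed in sign for some uncalled lists, such as the renal markers.

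Named genes were chosen by a rule fixed before the data were examined. For each comparison these were the 10 largest changes in each direction among called genes with a mean of at least 100 counts per library, and with both null libraries on the same side of both wild-type libraries. Where fewer than 5 genes passed in a direction, the 5 with the lowest p were named instead. Up to 4 members of each list with the lowest p, and ZNF598, EIF4E2, GIGYF1 and GIGYF2, were also named. Further genes called in both assays, the small non-coding RNA genes called in Ribo-seq (MIR7641-2 among them), and the gene families of the closing section, were chosen after their values were seen.

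The procedure was tested on counts simulated from the means, library sizes and dispersions of the real genes, with 200 genes changed. The RNA-seq test recovered 93% of 1.5-fold and 100% of 2-fold changes, and 9.8% of its 214 calls were false. In Ribo-seq 2.5% of 79 calls, and in translational efficiency 2.7% of 75 calls, were false. Replicates were compared by chi-square over genes: the statistic per degree of freedom lay between 2.94 and 10.6 in the 4 groups, so no pair differed by as little as counting noise, as copies of 1 library would. This does not show that the libraries came from separate cultures.

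Alternatives fixed before the data were examined were RLE scaling, no count filter, a filter at a mean of 100 counts, DESeq2 1.42.0, no robust estimation, the replicate number as a block, each replicate left out in turn, an adjusted p under 0.01, and a fold above 1.5. For translational efficiency they also included joint scaling, a term per culture and limma on log ratios, and for lists an estimated correlation and fry. Alternatives chosen after seeing the data were the genes of the authors' tables only, RefSeq protein-coding genes only, omission of genes in runs of neighbours, and removal of loess trends on gene length or GC content. Gene order and biotype came from RefSeq names on GRCh38.p14, matched for 25627 genes by symbol or synonym, and GC content and sequence came from GENCODE v29 transcripts. Neither is the build of the count tables, so no coordinates are given. The end genes of some runs are not reported here.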

Results

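HEK293T cells, an established human embryonic kidney line, were compared with a ZNF598-null derivative. ZNF598 is a ubiquitin ligase that recognises collided ribosomes and binds the 4EHP-GIGYF translational repressor complex. The series title places the comparison in a study of mRNA decay coupled to translation and induced by 4EHP and GIGYF1/2. RNA-seq measured mRNA abundance, and Ribo-seq counted the mRNA fragments protected by ribosomes (footprints). Each of the 4 groups held 2 libraries, described as biological replicates. The number of null clones was not given in the sources used here, so p-values measured the spread between 2 replicates per group. RNA-seq totals were 19755694 and 18736470 gene counts for wild-type replicates 1 and 2, and 25253283 and 28183610 for null replicates 1 and 2. Ribo-seq totals were 2535629 and 5476532 for wild-type and 5184757 and 3677923 for null. Protein-coding genes took between 97.1% and 97.3% of the RNA-seq counts and between 85.2% and 89.5% of the Ribo-seq counts. Small nuclear RNA genes, led by RNVU1-19, took between 3.19% and 5.62% of the Ribo-seq counts.

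ZNF598 fell in both assays. Its mRNA was at 102.3 ± 4.8 CPM (counts scaled to library size; SD, n = 2) in wild-type and 37.0 ± 6.2 CPM (SD, n = 2) in null libraries, 2.77-fold lower by edgeR (log2 fold change -1.47, SE 0.11, adjusted p = 5.0e-05). The libraries held 1988 and 1966 ZNF598 RNA-seq counts in wild-type and 1043 and 908 in null. ZNF598 footprints went from 69 and 160 counts to 5 and 13 counts, a log2 fold change of -3.73 (SE 0.33, adjusted p = 4.4e-05 by edgeR). The null libraries lay below both wild-type libraries in each assay, so the genotype labels and the ZNF598 counts went together. The change in translational efficiency of ZNF598, footprints relative to mRNA, was -2.27 on the log2 scale (SE 0.41) and missed the threshold (adjusted p = 0.078, edgeR interaction term). It passed without null replicate 2 (-3.52, adjusted p = 0.023) and without wild-type replicate 1 (-2.25, adjusted p = 0.040), and was -1.29 without null replicate 1 (adjusted p = 1). It also passed without a count filter (adjusted p = 0.020), with DESeq2 (adjusted p = 0.00018) and with a term per culture in edgeR (adjusted p = 1.6e-06). Among the partners of ZNF598, GIGYF2 mRNA rose 1.31-fold (log2 0.39, SE 0.09, adjusted p = 0.017 by edgeR), a call lost without null replicate 2 (log2 0.295, adjusted p = 0.23) and after removal of the dependence on gene length (log2 0.295, adjusted p = 0.053). GIGYF2 footprints were 0.44 higher (log2, SE 0.17) without passing the test (adjusted p = 0.33), which they did without wild-type replicate 2 (0.68, adjusted p = 0.0083). GIGYF1 mRNA differed by 0.0027 (SE 0.092) and EIF4E2 mRNA, which encodes the cap-binding protein 4EHP, by 0.016 (SE 0.073) on the log2 scale. The GIGYF1 footprint difference was 0.29 (SE 0.27) and that of EIF4E2 was -0.025 (SE 0.197), and neither passed (adjusted p = 0.71 and 0.97 by edgeR). In translational efficiency the log2 differences were 0.037 (SE 0.179) for GIGYF2, 0.28 (SE 0.29) for GIGYF1 and -0.014 (SE 0.206) for EIF4E2, with an adjusted p of 0.9999 for each.

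**Figure D1:**
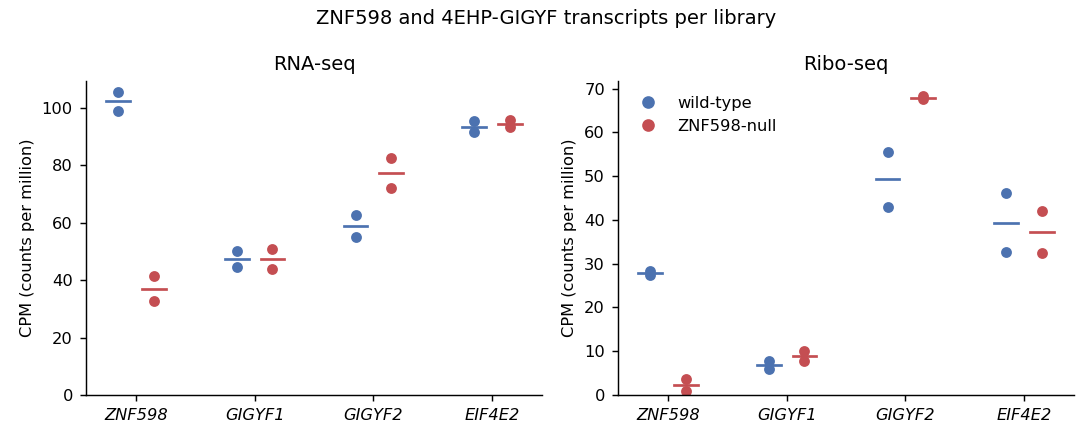
Levels of ZNF598, GIGYF1, GIGYF2 and EIF4E2 in each library, in CPM on linear axes from 0, for RNA-seq (left) and Ribo-seq (right); points are libraries and short bars the mean of 2 libraries per genotype. ZNF598 was lower in both null libraries, with footprints at 5 and 13 counts against 69 and 160 in wild-type.

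The loss of ZNF598 was accompanied by many mostly modest mRNA changes. Of 14991 genes tested with edgeR, 1427 rose and 1242 fell, and 312 and 363 of these changed more than 1.5-fold. The largest increases among well-counted genes were those of the long non-coding RNA LINC01419 (log2 fold change 2.16, SE 0.10), SAMD12 (1.68, SE 0.13) and BASP1, a membrane-bound protein abundant in neurons (1.47, SE 0.10). HSPA1B, an inducible Hsp70 chaperone, rose by 1.34 (SE 0.14) and IFIH1, a cytoplasmic sensor of double-stranded RNA, by 1.34 (SE 0.16). CROCC (1.25), CHRDL1 (1.22), NELL2 (1.22), TRIM58 (1.19) and ANXA1 (1.14) completed the 10 genes with the largest increases. The largest decrease among called genes with a mean of at least 100 counts was that of RPSAP58, named as a pseudogene of RPSA. It went from 618 and 549 counts to 13 and 8 (log2 -6.23, SE 0.18). TENM1, a teneurin adhesion protein (-2.49, SE 0.13), RUNX1T1, a transcriptional corepressor (-2.17, SE 0.14), and the pseudogene IPO5P1 (-2.06, SE 0.12) also fell. GPR50 (-1.55), NAPRT (-1.55), SATB1 (-1.54), ZNF598 itself (-1.47), the transcription factor HAND1 (-1.45) and ALDH1A2 (-1.42), an enzyme of retinoic acid synthesis, followed. Adjusted p-values of these 20 genes in edgeR lay between 1.5e-08 for RPSAP58 and 0.0020 for CHRDL1. SAMD12, TRIM58, NAPRT and SATB1 lie within runs of neighbouring genes that shifted together, TRIM58 and NAPRT against the direction of their run. Of the 28-base stretches of RPSAP58, 87.0% occur in its parent gene RPSA, but only 0.37% of those searched for IPO5P1 occur in IPO5. The number of changed genes depended on single libraries. It was 452 without null replicate 2, 1083 without null replicate 1 and 4960 without wild-type replicate 2, and DESeq2 called 1345.

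Chaperone and interferon-stimulated transcripts were higher in null cells. Of 20 tested heat shock genes, 11 rose and 0 fell in RNA-seq (14 and 0 adjusted over the list alone), with a median log2 fold change of 0.46. Examples were HSPA1B (1.34), the small heat shock protein HSPB1 (0.62, SE 0.07), the Hsp70 cochaperone BAG3 (0.80, SE 0.11) and DNAJB1 (0.54, SE 0.08). Of 37 tested interferon-stimulated genes, 19 rose and 3 fell (26 and 3 adjusted over the list alone), with a median of 0.47. The 3 that fell were the neighbouring genes PARP9 and DTX3L, which encode an ADP-ribosyltransferase family member and its partner ubiquitin ligase, and BST2 (-1.06, SE 0.11), which tethers budding virions. Proliferation genes included 11 of 40 that rose and 0 that fell (20 and 3 adjusted over the list alone), with a median of 0.26, among them MCM5 (0.76, SE 0.14), CDC6 (0.63, SE 0.10), MKI67 (0.49, SE 0.08) and TOP2A (0.41, SE 0.11). Of 33 proteasome genes 5 rose and 0 fell (also 5 and 0 adjusted over the list alone), with PSMD3 at 0.51 (SE 0.10), PSMD11 at 0.43 (SE 0.10), PSMD12 at 0.35 and PSMC2 at 0.27. Of 26 cholesterol synthesis genes 5 rose and 0 fell (also 5 and 0 adjusted over the list alone). They included SQLE, the squalene epoxidase gene, at 0.92 (SE 0.08), LSS at 0.39, FDPS at 0.31 and HSD17B7 at 0.33, of which SQLE lies in a run of genes that shifted together. Tested with limma camera at a preset correlation of 0.01, these 5 lists rose against the other genes, with adjusted p = 2.5e-05 for heat shock, 3.5e-07 for interferon-stimulated, 0.00095 for proliferation, 0.00073 for proteasome and 0.011 for cholesterol synthesis genes. None of the 5 calls held with an estimated correlation (adjusted p = 0.75 for each). The cholesterol call was also lost without wild-type replicate 1 (adjusted p = 0.076).

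Transcripts of ribosomal and respiratory-chain proteins were slightly lower in null cells. Of 78 tested cytosolic ribosomal protein genes 16 fell and 1 rose (also 16 and 1 adjusted over the list alone), 74 had values below 0, and the median log2 fold change was -0.15. RPSA (-0.49, SE 0.08), RPL15 (-0.37, SE 0.07), RPL32 (-0.43, SE 0.09) and RPL38 (-0.43, SE 0.09) had the lowest p-values, and RPSA, RPL15 and RPL32 lie in 1 run of genes that shifted together. Of 77 mitochondrial ribosomal protein genes 9 fell and 0 rose (2 and 0 adjusted over the list alone), with a median of -0.099. MRPS25 was at -0.46, MRPL55 at -0.41, MRPL47 at -0.36 and MRPL32 at -0.28, and MRPS25 and MRPL55 lie in runs. Of 77 nuclear-encoded oxidative phosphorylation genes 5 fell and 3 rose (5 and 1 adjusted over the list alone), with a median of -0.12, among them COX5A (-0.51, SE 0.07), COX5B (-0.31, SE 0.07), NDUFA5 (-0.47, SE 0.12) and COX6B1 (-0.32, SE 0.08). Camera gave adjusted p = 3.5e-07, 0.0037 and 0.0029 for these 3 lists, and adjusted p = 0.75 for each with an estimated correlation. After the dependence of each library on gene length was removed, the cytosolic ribosomal protein median was -0.085 and still passed (adjusted p = 0.0043), while the mitochondrial ribosomal protein and oxidative phosphorylation calls were lost (medians of -0.056 and -0.037, adjusted p = 0.24 and 0.36). The oxidative phosphorylation call was also lost without null replicate 2 (adjusted p = 0.091).

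The lists closest to the function of ZNF598 were not called as lists in RNA-seq. Of 29 genes of ribosome collision sensing and ribosome-associated quality control, 6 rose and 2 fell (6 and 3 adjusted over the list alone; adjusted p = 0.16 by limma camera). ASCC1 (0.42, SE 0.10), the unfoldase gene VCP (0.77, SE 0.17) and GCN1 (0.30, SE 0.07) rose, and ZNF598 fell. Of 14 genes of the 4EHP-GIGYF complex and its partners 3 rose and 2 fell (4 and 2 adjusted over the list alone; adjusted p = 0.31). TNRC6B (0.54, SE 0.10) and GIGYF2 rose, and EIF4EBP1 (-0.52, SE 0.07) and EIF4E3 (-0.28, SE 0.07) fell, of which EIF4E3 lies in a run. Of 35 deadenylation, decapping and 5-prime decay genes 1 rose, the exonuclease gene XRN1 (0.34, SE 0.08), and 4 fell, including LSM3 (-0.41), DDX6 (-0.31, SE 0.08) and CNOT7 (-0.28, SE 0.08); LSM3 lies in a run. These counts were also 1 and 4 adjusted over the list alone (adjusted p = 0.65 by limma camera). Of 18 nonsense-mediated decay factors 4 rose and 2 fell (9 and 2 adjusted over the list alone; adjusted p = 0.083 by limma camera), with UPF2 at 0.57 (SE 0.10), NBAS at 0.39, UPF3B at 0.45 and MAGOHB at -0.32.

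Stress and growth lists were mixed. Among 36 ATF4 targets of the integrated stress response 6 rose and 3 fell (7 and 3 adjusted over the list alone; adjusted p = 0.63 by limma camera). ATF3 (0.68, SE 0.08) and CEBPB (0.50, SE 0.09) rose, and SLC7A5 (-0.46, SE 0.07) fell. Among 24 unfolded protein response genes of the endoplasmic reticulum 4 rose and 7 fell (5 and 7 adjusted over the list alone; adjusted p = 0.33 by limma camera), with XBP1 at 0.45, SEC24D at 0.50, DERL3 at -0.71 and MANF, which lies in a run, at -0.47. Among 36 immediate-early and AU-rich-element mRNAs 9 rose and 5 fell (also 9 and 5 adjusted over the list alone; adjusted p = 0.29 by limma camera). The transcription factor gene JUN rose 2.12-fold (1.09, SE 0.09), KLF6 by 0.51 and CYR61 by 0.53, while MYC fell (-0.56, SE 0.09) within a run of genes that were mostly higher. Of 29 p53 targets 1 rose, TP53I3 (0.57, SE 0.09), and 5 fell (1 and 6 adjusted over the list alone; adjusted p = 0.17 by limma camera), including BBC3 (-0.59), CCNG1 (-0.33) and TNFRSF10B (-0.30). Among 32 hypoxia and glycolysis genes 5 rose and 4 fell (9 and 5 adjusted over the list alone; adjusted p = 0.29 by limma camera), with ENO2 at 0.87, NDRG1, which lies in a run, at 0.75, ADM at -0.82 and PDK1 at -0.42. Of 46 translation initiation and elongation factors 5 rose and 2 fell (also 5 and 2 adjusted over the list alone; adjusted p = 0.50 by limma camera), with EIF4A2 at 0.57 (SE 0.07), EIF3A at 0.44, EIF3H at 0.35 and EIF1B at -0.45; EIF3H and EIF1B lie in runs. Of 20 cytosolic aminoacyl-tRNA synthetase genes AARS (0.47) and VARS (0.32) rose, and 0 passed adjusted over the list alone (adjusted p = 0.17 by limma camera). Of 19 selenoprotein genes 0 rose and 6 fell (2 and 6 adjusted over the list alone; adjusted p = 0.22 by limma camera), including GPX1 (-0.53, SE 0.08), SEPHS2 (-0.44), GPX4 (-0.46) and SELK (-0.30), and GPX1, SEPHS2 and SELK lie in runs. None of the 15 tested replication-dependent histone genes was called by edgeR (lowest p for HIST3H2A, 0.26, adjusted p = 0.11), and camera gave adjusted p = 0.60.

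Markers of other cell identities moved in both directions. Of 20 tested neuronal markers 5 rose and 1 fell (6 and 2 adjusted over the list alone; adjusted p = 0.090 by limma camera), including MAPT at 1.01 (SE 0.09), ENO2 at 0.87, INA at 0.57 and TUBB3 at 0.53. Of 14 renal and epithelial markers 3 rose and 2 fell (4 and 2 adjusted over the list alone; adjusted p = 0.64 by limma camera), with KRT18 at 0.52, EMX2 at 0.53, EYA1 at -1.19 and CDH1 at -0.73; the median of this list was 0.083 and its mean -0.072. Of 23 mesenchymal and extracellular matrix markers 2 rose and 3 fell (4 and 3 adjusted over the list alone; adjusted p = 0.49 by limma camera), with COL1A1 at 0.48, ZEB1 at 0.41, SNAI2 at -1.16 (SE 0.09) and SPARC at -0.30.

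Counts of 28 genes rose and those of 27 fell among 13800 genes tested in Ribo-seq with edgeR. Of these 55 genes, 42 were also called when only protein-coding genes were tested. The calls included the small non-coding RNA genes SNAR-B1, SNAR-B2, SNORD102, SCARNA28, MIR3609 and MIR7641-2, whose reads need not be ribosome footprints. Among well-counted protein-coding genes, APOE, which encodes a lipid carrier protein, rose 2.49-fold (log2 1.31, SE 0.20, adjusted p = 0.0068), ATAD2 by 1.31 (SE 0.21), the small GTPase gene RHOB by 1.23 (SE 0.15), HSPA1B by 1.19 (SE 0.17), HSPA1A by 1.19 (SE 0.17), TRIB1 by 1.12 (SE 0.22) and C11orf80 by 1.11 (SE 0.23). HSPA1A and HSPA1B are near-identical copies and are uncertain one by one: HSPA1A had 42, 39, 45 and 72 RNA-seq counts but between 3876 and 18226 footprint counts. The uncharacterised loci LOC103091866 (2.13), LOC388692 (1.91) and LOC101927550 (1.55) had the largest increases among called genes with a mean of at least 100 counts. LOC103091866 and LOC388692 averaged 11610 and 49800 Ribo-seq counts per library. Whether reads of these loci were ribosome footprints was not tested. Only 8 well-counted genes fell: CALCB, a calcitonin-related peptide gene (-1.21, SE 0.18), the fibrillin gene FBN2 (-1.14, SE 0.16), the endocytic receptor gene LRP2 (-1.09, SE 0.18), DUXAP8 (-0.87), LINC01296 (-0.85), DUXAP10 (-0.84), RBM27 (-0.82) and the proteoglycan gene VCAN (-0.81, SE 0.15). The related transcripts DUXAP8, DUXAP10 and LINC01296 are uncertain one by one, and ATAD2, TRIB1 and RBM27 lie in runs of genes that shifted together, RBM27 against the direction of its run. Adjusted p-values of these 18 genes lay between 4.4e-05 for LOC388692 and 0.045 for RBM27 and C11orf80. The footprint calls of HSPA1A, HSPA1B, TRIB1 and C11orf80 were lost without null replicate 2 and those of FBN2 and LRP2 without null replicate 1. The calls of DUXAP8, DUXAP10, LINC01296, RBM27 and VCAN were lost without either one, and DESeq2 did not call TRIB1, C11orf80, LRP2, DUXAP8 or RBM27. The number of changed genes was 1237 without wild-type replicate 2, 279 without wild-type replicate 1, 103 without null replicate 1, 350 without a count filter and 24 with DESeq2. On simulated counts with the Ribo-seq depth and spread, 63.6% of 2-fold and 14.4% of 1.5-fold changes were recovered among 13589 genes, against 100% and 93% in RNA-seq among 14852 genes.

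The same 8 gene lists were called in Ribo-seq as in RNA-seq, in the same directions. Heat shock genes had a median of 0.39 (2 of 20 called higher, 9 adjusted over the list alone) and interferon-stimulated genes of 0.34 (1 of 31 called higher and 1 lower, 7 and 2 adjusted over the list alone). The 2 called heat shock genes were the near-identical copies HSPA1A and HSPA1B, which may be 1 signal. The 2 called interferon-stimulated genes were IFIH1 (1.74, SE 0.35) and BST2 (-1.21, SE 0.25). Medians were 0.19 for 40 proliferation genes (0 called, 2 higher adjusted over the list alone), 0.13 for 33 proteasome genes (0 called by edgeR, also adjusted over the list alone) and 0.11 for 26 cholesterol synthesis genes, where SQLE (0.83, SE 0.15) was called on both scales. Medians were -0.18 for 79 cytosolic ribosomal protein genes, -0.11 for 77 mitochondrial ribosomal protein genes and -0.15 for 77 oxidative phosphorylation genes, with 0 members called by edgeR in any of these 3 lists, also adjusted over the list alone. Camera's adjusted p-values were 5.3e-06 for heat shock, 0.0012 for interferon-stimulated, 0.013 for proliferation, 0.014 for proteasome, 0.036 for cholesterol synthesis, 7.0e-06 for cytosolic ribosomal protein, 0.0055 for mitochondrial ribosomal protein and 0.0037 for oxidative phosphorylation genes. None held with an estimated correlation (adjusted p = 0.78 for each). Without wild-type replicate 1 (adjusted p from 0.13 to 0.82) or null replicate 2 (0.16 to 0.18) the mitochondrial ribosomal protein, oxidative phosphorylation, cholesterol synthesis, proliferation and proteasome calls were lost. Without null replicate 1 the cholesterol synthesis and proteasome calls were lost (adjusted p = 0.067 and 0.081). Removing the dependence on gene length ended the calls of the cytosolic ribosomal protein (median -0.060, adjusted p = 0.095), mitochondrial ribosomal protein (-0.063, adjusted p = 0.24), oxidative phosphorylation (-0.045, adjusted p = 0.39) and cholesterol synthesis lists (0.081, adjusted p = 0.054). The cholesterol synthesis call was also lost without genes in runs (adjusted p = 0.11), with a median of 0.103 over 25 genes against 0.108 over 26. The other 16 tested lists did not pass in Ribo-seq (lowest adjusted p = 0.092, selenoproteins). Members called in them were ZNF598, JUN (1.07, SE 0.16), ATF3 (1.02, SE 0.20) and the neuronal intermediate filament gene INA (0.87, SE 0.18).

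**Figure D2:**
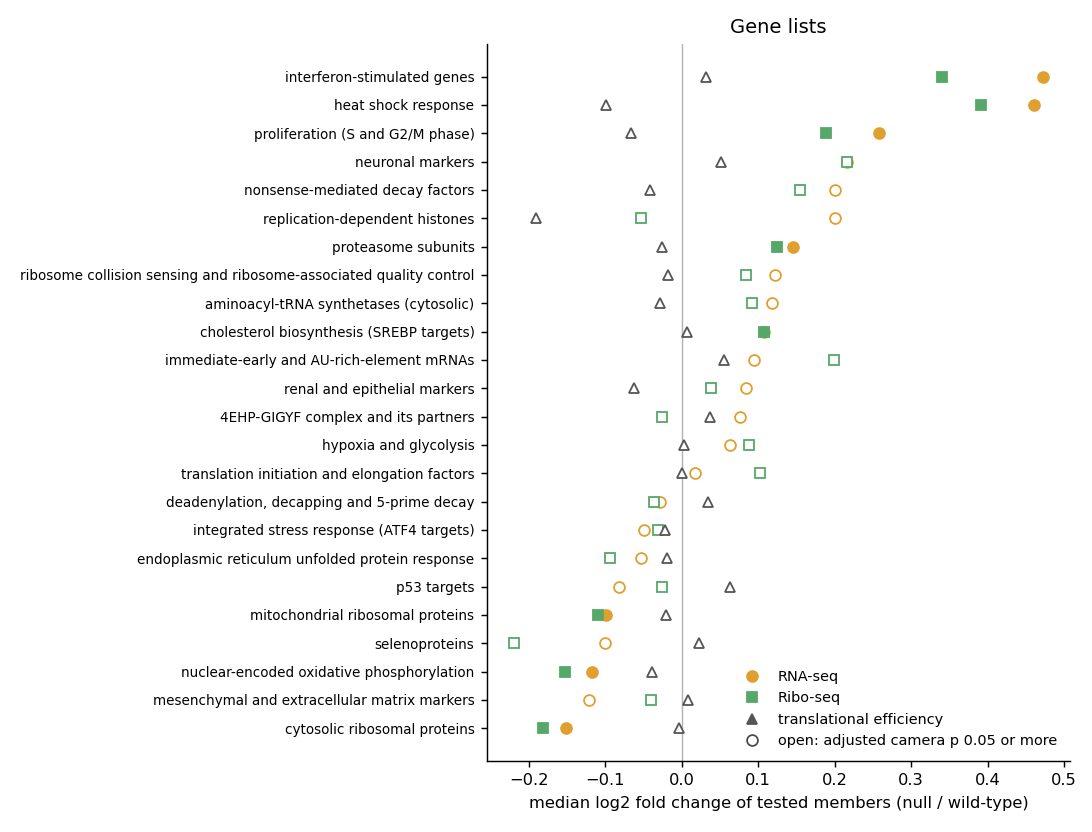
Median log2 fold change (null over wild-type) of the tested members of 24 gene lists in RNA-seq (circles), Ribo-seq (squares) and translational efficiency (triangles); filled symbols mark an adjusted camera p under 0.05 at the preset correlation. The 8 lists called in RNA-seq were the 8 called in Ribo-seq, and 0 were called in translational efficiency.

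Translational efficiency, measured from counted reads, differed in 6 of 12362 genes by the edgeR interaction term. It rose for RPSAP58 (log2 6.23, SE 0.22, adjusted p = 4.2e-09), RPSAP9 (2.92, SE 0.21, adjusted p = 1.3e-05), DTX3L (7.01, SE 0.51, adjusted p = 1.3e-05), PARP9 (5.74, SE 0.55, adjusted p = 0.00026) and IPO5P1 (1.85, SE 0.20, adjusted p = 0.0011). It fell for TSSC2 (-1.83, SE 0.28, adjusted p = 0.029). In each case the RNA-seq value changed while the footprint test was not passed. RPSAP58 mRNA fell by 6.23 and its footprints differed by 0.013 (SE 0.140). RPSAP9 mRNA fell by 2.91 and its footprints differed by 0.011 (SE 0.144). Footprint counts of RPSAP58 and RPSAP9 were 62.8% to 65.5% and 42.3% to 44% of those of RPSA across the 4 libraries. Their wild-type RNA-seq counts were only 1.01% and 1.05%, and 0.23% and 0.216%, of those of RPSA. Footprint reads shared with RPSA may therefore account for the calls of RPSAP58 and RPSAP9. DTX3L had 103 and 138 RNA-seq counts in wild-type and 1 and 1 in null libraries, and 40 and 97 footprint counts in wild-type against 81 and 60 in null libraries. PARP9 had 90 and 82 RNA-seq counts in wild-type and 1 and 1 in null, and 21 and 44 footprint counts against 23 and 16. The 39 PARP9 footprint counts over both null libraries (exact 95% Poisson interval 27.7 to 53.3) lay below the 69.4 expected at the wild-type level. For each of DTX3L and PARP9 the 2 RNA-seq counts over both null libraries have an exact 95% Poisson interval of 0.24 to 7.22, against 330.8 and 236.1 counts expected at the wild-type level, and their fitted fold changes depend on the handling of low counts. IPO5P1 mRNA fell by 2.06 with a footprint difference of -0.20 (SE 0.19), and TSSC2 mRNA rose by 2.01 (SE 0.20) with a footprint difference of 0.16 (SE 0.22). Only RPSAP58 reached a mean of 100 counts in both assays; the other 4 higher genes and TSSC2 are named for their low p-values. The next lower genes by p, which did not pass, were SP100 (-3.01, adjusted p = 0.063), ZNF598, SP140L (-3.66, adjusted p = 0.080) and LOC400655 (-3.53, adjusted p = 0.12). SP100, SP140L and LOC400655 passed without a count filter (adjusted p = 0.010, 0.026 and 0.035) and with a term per culture (adjusted p = 0.00014, 0.0023 and 0.00075), SP100 also with DESeq2 (adjusted p = 0.015) and without wild-type replicate 1 (adjusted p = 0.0026), and LOC400655 without wild-type replicate 2 (adjusted p = 0.047). The calls of IPO5P1 and TSSC2 were lost without either null replicate and that of PARP9 without null replicate 1. The number of called genes was 31 and 30 without wild-type replicate 1 and 2, and 3 without null replicate 1, and limma on log ratios called 2, RPSAP58 and DTX3L.

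**Figure D3:**
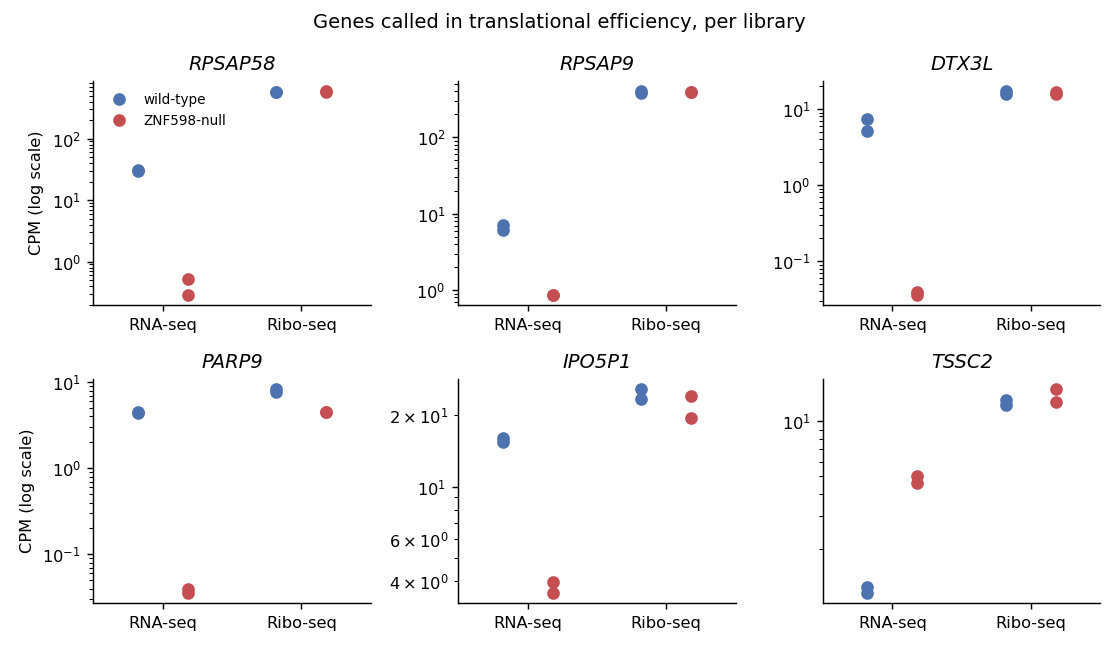
Levels of the 6 genes called in translational efficiency, in CPM on log axes, with 1 point per library, wild-type beside ZNF598-null, for RNA-seq and Ribo-seq. RNA-seq levels separated by genotype in all 6 panels, while footprint differences did not pass the edgeR test, which does not show that footprints were unchanged. RPSAP58 went from 618 and 549 to 13 and 8 RNA-seq counts.

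No gene list was called in translational efficiency. List medians ranged from -0.19 for 15 histone genes to 0.063 for 28 p53 targets, and the lowest adjusted camera p was 0.82, for interferon-stimulated genes. Of 24 lists tested, 1 had an unadjusted camera p under 0.05, 0 with an estimated correlation and 1 with fry. Members called in any list were DTX3L and PARP9 only. On simulated counts the interaction test recovered 60.6% of 2-fold and 13.4% of 1.5-fold footprint changes among 12173 genes.

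Footprint changes correlated with mRNA changes across genes. Over 12362 genes tested in both assays, Pearson's r of the log2 fold changes was 0.51 and Spearman's rho 0.61, across genes that are not independent replicates. Among the 2376 genes called in RNA-seq, 2184 (91.9%) had a footprint change of the same sign, against 73.55% of all 12362 genes, with a median footprint change of 0.33 in the RNA direction against a median absolute RNA change of 0.40. Of the genes called in both assays 21 rose in both, against 2.87 expected of independent lists, 19 fell in both, against 1.63, and 0 moved in opposite directions. Another 6 genes called in Ribo-seq were tested but not called in RNA-seq. They were LOC103091866 (0.49 in RNA-seq and 2.13 in Ribo-seq), LOC388692 (-0.026 and 1.91), LOC101927550 (0.036 and 1.55), HSPA1A (0.070 and 1.19), C11orf80 (0.12 and 1.11) and MIR7641-2 (-0.90 in RNA-seq, and 0 and 0 footprint counts in wild-type against 31 and 9 in null libraries). HSPA1A is uncertain apart from its near-identical copy HSPA1B, which was called in both assays (1.34 and 1.19). For these 6 genes the difference between assays did not pass the edgeR interaction test (adjusted p from 0.063 for LOC388692 to 0.9999 for LOC103091866). A further 9 genes called in Ribo-seq were not tested in RNA-seq. Genes that fell in both included TENM1 (-2.49 in RNA-seq and -2.37 in Ribo-seq), RUNX1T1 (-2.17 and -2.13), SATB1 (-1.54 and -2.35), HAND1 (-1.45 and -1.47), ALDH1A2 (-1.42 and -1.32) and CALCB (-1.37 and -1.21). Genes that rose in both included RHOB (1.14 and 1.23), APOE (1.10 and 1.31), ATAD2 (1.08 and 1.31), JUN (1.09 and 1.07) and SQLE (0.92 and 0.83). Median standard errors were 0.087 in RNA-seq and 0.19 in Ribo-seq.

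**Figure D4:**
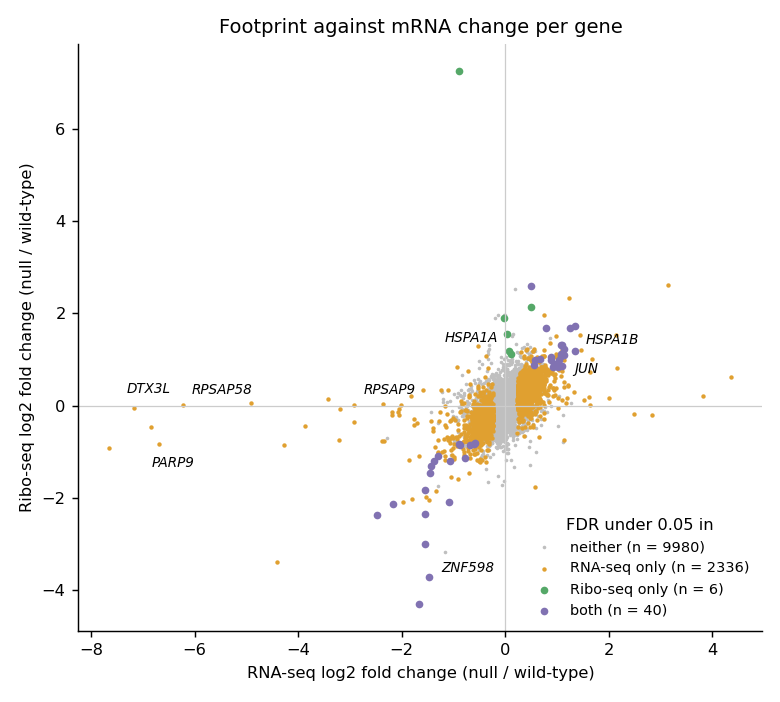
Log2 fold change (null over wild-type) in Ribo-seq against RNA-seq for the 12362 genes tested in both, coloured by the assay in which edgeR called them. ZNF598 lies low on both axes, while RPSAP58, RPSAP9 and DTX3L lie at negative RNA-seq values with footprint values near 0.

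At an adjusted p under 0.05 the authors' deposited table for RNA-seq listed 978 higher and 849 lower genes, that for Ribo-seq 62 and 51, and that for translational efficiency 8 and 3. Fold changes computed here correlated with those of the authors' deposited tables at r = 0.997, 0.9995 and 0.968, across the 10426, 10299 and 10295 genes tested in both. Of the calls in the authors' deposited tables, 1650 of 1827 in RNA-seq, 38 of 113 in Ribo-seq and 5 of 11 in translational efficiency were also called here, all in the same direction. The translational efficiency calls in the authors' deposited table were DTX3L (log2 7.70), RPSAP58 (6.56), RPSAP9 (3.08), IPO5P1 (1.91), NANOS1 (1.51), TMEM160 (0.91), DDX19B (0.73), RPSA (0.50), ZNF770 (-0.62), TSSC2 (-2.01) and ZNF598 (-2.13). In the authors' deposited table the translational efficiency of ZNF598 fell with an adjusted p of 3.4e-06.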

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

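The tests of pseudogene sequences against their parent genes, the search with mismatches, the requirement that searched transcripts reach 80% of the counted length, and the check of RNA-seq depth for DTX3L and PARP9 were chosen only after the results had been seen. The genotype effect differed between RNA-seq and Ribo-seq, by the edgeR interaction term, for RPSAP58 (log2 6.23), RPSAP9 (2.92), DTX3L (7.01), PARP9 (5.74), IPO5P1 (1.85) and TSSC2 (-1.83).

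In all 6 genes RNA-seq changed while footprints did not pass the test, and candidate explanations were reads shared with other genes and low depth. For low RNA-seq depth, the upper bound of the null count of DTX3L and PARP9 was 7.22, against 330.8 and 236.1 counts expected at the wild-type level. Both genes were called from these same counts, so the check could hardly have come out otherwise and is no separate evidence. Its interval covers counting error only. Shared reads may account for RPSAP58 and RPSAP9: of their 28-base stretches (footprint size) 87.0% and 51.8% occur unaltered in RPSA, and 100% and 95.7% with up to 2 mismatches, in transcripts reaching 64.4% and 61.7% of the counted length. RPSAP58 footprints were 65.5%, 62.8%, 65.4% and 63.3% of the RPSA footprints in wild-type replicates 1 and 2 and null replicates 1 and 2, while its RNA-seq ratio to RPSA fell by 5.75 on the log2 scale. For IPO5P1 only 0.37% of stretches occur in IPO5 (5.91% with up to 2 mismatches), and 20.23% in any other gene. Its ratio to IPO5 fell by 2.32 in RNA-seq and by 0.44 in footprints (log2). The bound of 10% first set for IPO5 would argue against sharing. Sharing was left open for IPO5P1 because the searched transcripts reach 52.4% of the counted length. DTX3L and PARP9 stayed open jointly (11.01% and 3.10% in other genes, the first above and the second below 10%). For TSSC2 27.65% of stretches occur in other genes (at most 6.89% in 1 gene, ALG1). No bound was set for TSSC2, so sharing stays open there too. An effect of the genotype on translation remains untested.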

How the results depend on the processing

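Alternatives limited to the authors' genes, protein-coding genes or genes outside runs, and those removing length or GC trends, were chosen after seeing the data; the list tests under changed scaling, filters, joint scaling or a culture term were also added then. ZNF598 kept its direction and call in RNA-seq (log2 -1.65 to -1.31) and Ribo-seq (-4.80 to -2.93) under all alternatives run; the strict filter leaves it out of Ribo-seq and translational efficiency. The cause was not tested for the changes below, except that stricter thresholds call fewer genes and filters change the genes tested. RNA-seq calls (2669) became 1345 with DESeq2, 821 at an adjusted p under 0.01, 675 with a fold above 1.5, and 452 to 4960 with 1 replicate left out (without null replicate 2 and without wild-type replicate 2). Ribo-seq calls (55) became 350 without a filter, 18 with the strict filter, 24 with DESeq2, 18 at 0.01, 31 after GC correction and 58 to 1237 with 1 replicate left out. Translational efficiency calls (6) became 18 without a filter, 1 with the strict filter, 14 with DESeq2, 44 with a culture term, 2 with limma on log ratios, 3 among protein-coding genes and 3 to 31 with 1 replicate left out. Left-out fits assume that the lone library varies like the others. The translational efficiency of ZNF598 passed without a filter (-2.29), with DESeq2 (-2.27) and with a culture term (-2.28), and was -3.52 to -1.29 with 1 replicate left out; its adjusted p ranged from 1.6e-06 to 1. List calls (8 in each assay) became 0 with an estimated correlation or fry in both assays, 7 to 13 in RNA-seq and 3 to 11 in Ribo-seq with 1 replicate left out, and 5 in Ribo-seq after length correction, of which 4 were among the 8 and the fifth was histones (adjusted p = 0.015, median turned from -0.054 to 0.10). At an unadjusted p under 0.05 fry gave 4 lists in RNA-seq and 0 in Ribo-seq, and the estimated correlation 0 in both. No list was called in translational efficiency under any of 17 alternatives. The correlation of RNA-seq with Ribo-seq changes was 0.76 with the strict filter and 0.39 to 0.48 with 1 replicate left out.

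With the replicate number as a block, calls rose to 5625 in RNA-seq, 480 in Ribo-seq and 29 in translational efficiency, where ZNF598 passed (-2.29). Nothing in the labels ties the 2 pairs together beyond the number. Replicate differences correlated at 0.20 (RNA-seq) and 0.13 (Ribo-seq) between genotypes, and at 0.24 (wild-type) and 0.11 (null) between assays, where the culture term treats libraries of the same number as 1 culture. SP100, SP140L and LOC400655 passed with the block (adjusted p = 0.0022, 0.010 and 0.0063). The block kept the number of called lists at 8, 8 and 0.

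Directions turned for genes that were not called: GIGYF1 mRNA (-0.0018 with the strict filter, -0.053 and -0.00032 after length and GC correction, -0.098 to 0.10 with 1 replicate left out, -0.077 without wild-type replicate 2), EIF4E2 mRNA (-0.0086 to 0.047), EIF4E2 footprints (-0.27 to 0.21), and in translational efficiency GIGYF2 (-0.036 to 0.18) and EIF4E2 (-0.32 to 0.23 with 1 replicate left out, 0.0098 with joint scaling, 0.0070 after GC correction). Values under the alternatives were compared for 22 genes in RNA-seq, 21 in Ribo-seq and 12 in translational efficiency. These were the genes named for the largest changes or lowest p, and GIGYF1, GIGYF2 and EIF4E2. Genes named only as list members were not included. Of these values, 354 of 364 in RNA-seq, 299 of 342 in Ribo-seq and 195 of 223 in translational efficiency kept direction and side of the threshold. So did 100 of 120 values of the 8 called lists in RNA-seq and 86 of 120 in Ribo-seq. Most of the genes were picked for large changes or low p, so these shares do not describe called genes in general. At the depth (2535629 to 5476532 counts) and spread of Ribo-seq, 63.6% of simulated 2-fold and 14.4% of 1.5-fold changes were recovered, and the share due to depth alone was not tested.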

Other observations

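The test of footprints in the runs of neighbouring genes, the corrections for gene length, GC content and runs, and the families in the next paragraph were chosen only after the data had been seen.

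Clustered protocadherin genes, which encode neuronal adhesion proteins, were higher in null cells: of 27 tested, 22 rose and 0 fell in RNA-seq, with a median log2 fold change of 0.42, among them PCDHGC4 (0.48, SE 0.10) and PCDHGC3 (0.43, SE 0.09). These genes lie side by side, 22 of them in 1 run described below, and many share exons, so their reads cannot be assigned one by one. Of 14 alpha and beta tubulin genes 9 rose and 0 fell in RNA-seq, with a median of 0.38, including TUBB4A (0.54, SE 0.10), TUBA1A (0.58, SE 0.12) and TUBB2A (0.46, SE 0.10), and in Ribo-seq 15 of 16 had values above 0 with 0 called by edgeR. In Ribo-seq 10 of 12 protocadherins had values above 0, also with 0 called. Of 427 zinc finger genes named ZNF, leaving out ZNF598, 28 rose and 48 fell in RNA-seq, with a median of -0.096. Medians with RLE scaling had the same signs (0.42, 0.39 and -0.091).

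Neighbouring genes shifted together in RNA-seq in 8 runs, found in windows of 40 genes (11708 placed of 11819 with a mean of at least 100 counts) whose median passed the 95% bound of 1000 shuffles (0.178): 120 genes from EIF3E to ZNF252P, for example, had a median of 0.33 with 111 higher. Gene length and GC content were argued against, as the median run shift was 101% of its size after the stronger correction. The largest shift of a run between libraries of 1 genotype was 36.1% of its genotype shift. As runs were chosen for their genotype shift, that comparison favours a small share. The same window search on the differences between the 2 libraries of each genotype found 0 windows past its bound. Variation between cultures is not excluded, because the origin of the libraries is unknown. A candidate explanation is a chromosome-scale difference between the cell lines, such as a copy number difference acquired by a clone. Footprint and RNA-seq changes had the same sign in 73.55% of all 12362 genes. Agreement of footprints with RNA within runs would therefore arise under other causes too and cannot single this one out. Footprints had the direction of the RNA in 7 of 8 runs, the exception being the run from ANKHD1 to TIGD6 (footprint median -0.017). That run of 60 genes, 43 of them tested in Ribo-seq, holds the 22 protocadherin genes whose reads cannot be assigned one by one. It is therefore a weak case on either side. A chromosome-scale difference cannot be told apart from regional regulation that follows ZNF598 loss, because DNA was not analysed here and the genotype coincides with the cell line.

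The 3 lists that fell, cytosolic ribosomal proteins, mitochondrial ribosomal proteins and oxidative phosphorylation, hold short genes (median lengths of 880, 1359 and 975 bases against 3218 for tested genes), and gene length, GC content and the runs could account for this. GC content and runs were argued against, because the medians in RNA-seq hardly moved. They were -0.16, -0.109 and -0.125 after GC correction, and -0.145, -0.0944 and -0.115 without genes in runs, against -0.152, -0.0993 and -0.118 uncorrected. At the preset correlation the highest adjusted camera p of the 3 was 0.00188 after GC correction and 0.00351 without genes in runs. With an estimated correlation the 3 lists did not pass even uncorrected (adjusted camera p = 0.745 for each). After length correction the medians in RNA-seq went from -0.15 to -0.085 (median absolute deviation 0.088 and 0.095), from -0.099 to -0.056 (0.119 and 0.117) and from -0.12 to -0.037 (0.106 and 0.100), and the last 2 calls ended because the shift shrank (highest adjusted p 0.361), while cytosolic ribosomal proteins stayed past the threshold (0.0043). Length also tracked the difference between the 2 null RNA-seq libraries (Spearman's rho 0.24 across genes, 0.033 for the wild-type pair and 0.21 for the genotype effect) and between the wild-type Ribo-seq libraries (0.28). A length-dependent library effect and a change in expression therefore cannot be told apart for these lists.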
